A study of Homo sapiens with 2 samples.

How the data were processed

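Gene expression was measured on 2 Agilent 1-colour arrays (design 026652, genome build hg19, per the file headers), 1 for LNCaP cells with the empty plasmid and 1 for cells with the CREB5 plasmid. Groups were taken from the treatment label of each sample. Per the file headers, both arrays lay on the same slide and were read in the same scan, so no batch could be compared. RNA was amplified and labelled with Cy3 with an Agilent kit, per the labels' protocols. Per the file headers, the scanner image was read with Feature Extraction 11.0.1.1, which subtracted the background, removed a spatial trend and wrote a processed signal per spot, a linear intensity not normalized between arrays. The deposited files also hold the median pixel intensity of each spot and of its local background and other values, flags for saturated spots, for outlier spots and for spots well above background. The value table deposited by the authors holds log2 values, and RMA is named in the submitters' processing notes, without a version. Its scale, centring and direction were found from the values. Both columns have a median of 5.81 and, when sorted, differ by at most 0.0063, as after quantile normalization. They follow the log2 processed signal of the same array (Pearson's r across probes 0.991 and 0.992), with no centring of genes. The differences between its columns correlate across probes, dim ones included, with the probe differences used here at r = 0.816, in the same direction.

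Signals were taken as log2 of the processed signal minus the 75th percentile of each array (599 on the empty-vector array and 498 on the array labelled CREB5). Control spots and the 362 and 482 spots flagged as outliers were left out. Spots of a probe were averaged on the log2 scale, and then the probes of a gene that were well above background on at least 1 array. A gene was measured on both arrays if at least 1 of its probes was well above background on each. A gene well above background on 1 array only has a bound, its signal on that array over the higher of the dim value and the lowest signal well above background on the other array, both scaled. The bound allows for no spot error. Probes were named through their transcript accessions, without versions, from a RefSeq gene table of a later assembly (GRCh38), from which no coordinates were used. This named 25771 of 34127 probes, and the other 8356 kept their accession.

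With 1 array per group no test between the conditions was possible, and no p-value was computed. Differences are CREB5-labelled minus empty-vector array on the log2 scale, counted at a fixed 2-fold. For each gene list, the median difference was set against 10000 random lists of the same size, drawn within 20 bins of mean signal. That percentile describes these 2 arrays and does not test the conditions. The technical error came from probes with 10 spots on each array, 875 of them measured on both arrays out of 999. The median local background was 17 on both arrays, and the 153 negative control spots had a mean processed signal of 1.65 and 1.42. The median coefficient of variation of replicate spots was 4.44% on the empty-vector array and 6.97% on the other, per the file headers.

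The 38 gene lists and the rule for named genes were fixed before the data were examined. The rule took CREB5 and the CREB/ATF family, and then up to 12 genes in each direction with the largest difference. Those had to carry a symbol that is not a placeholder, be measured and unsaturated on both arrays, lie above the 25th percentile of signal, have all probes pointing in the same direction, and be at least 2-fold apart in the main setting, with normexp, after quantile normalization and in the authors' table. It then took the 5 highest bounds in each direction and, for each list described, up to 4 members with the largest difference and any member with a bound of at least 4-fold. Only 11 higher and 8 lower genes met the rule. Some list members that the rule would name are not reported here.

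The 8 alternatives fixed in advance were normexp background correction (offset 50), quantile normalization, scaling to the median of detected probes, loess of the difference on the mean level (span 0.3), the authors' value table, no filter on dim probes, a stricter filter, and the brightest probe of each gene. Normexp had been planned on the mean spot signal and was run on the median spot signal, the column used here. A further 3 alternatives were chosen after seeing the data: protein-coding genes alone as background of the lists, genes with 2 or more measured probes alone, and a 2-fold call only where 2 or more probes were all 2-fold apart.

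The calculation was tested on simulated data drawn for 22299 genes of this comparison with the measured spot noise. Of 50 genes each set 1.5-, 2.5- and 4-fold apart, 8%, 92% and 100% were called 2-fold, and 5 of 22099 unchanged genes were called. A list of 25 genes raised 1.3-fold reached percentile 100, and 12 of 200 unchanged lists fell outside the central 95%. The simulated noise was Gaussian, without the rare far-off spots seen on the arrays. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and R 4.3.3 with limma 3.58.1; figures were drawn with matplotlib 3.10.9.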

Results

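The data were gene expression profiles of LNCaP, an androgen-sensitive human prostate cancer cell line that expresses the androgen receptor. Cells were transfected with an empty plasmid (PcDNA3-1) or with the same plasmid carrying the sequence of CREB5, a basic leucine zipper transcription factor of the CREB/ATF family. Total RNA was labelled with Cy3 and hybridised to Agilent 1-colour arrays. The series held 2 arrays, 1 per condition, so differences between them had no replicate check, no p-value was computed, and the number of arrays limited the precision. The comparison asks which transcripts differ in level when CREB5 is overexpressed. Each array carried 43118 non-control spots of 34127 probes. Signal was well above background for 82.5% of these spots on the empty-vector array and for 84.0% on the array labelled CREB5, and no spot was saturated. In all, 22311 genes or unnamed transcripts were measured on both arrays, and 16701 of them carried a gene symbol. The levels of the measured genes correlated across genes with Pearson's r = 0.993 between the arrays (genes are not independent replicates). The only measured error was technical. Among probes printed 10 times on each array, the spot-to-spot SD of the log2 difference fell from 0.32 at the lowest levels to 0.09 at the highest, and the SD at a gene's own level is quoted below as its spot SD.

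CREB5 itself was read by 1 probe, whose signal was 49.1 on the empty-vector array and 43.2 on the array labelled CREB5. After scaling, the difference was 0.08 on the log2 scale, or 1.06-fold, with a spot SD of 0.27. The probe was well above background on both arrays. Its place relative to the cloned part of CREB5 is not known here, so it checks nothing about the plasmid. The directions given below therefore rest on the labels, and the array is called the CREB5-labelled array throughout. All 17 genes of the CREB/ATF family and its coactivators fixed before the data were examined were measured, and 0 of them were 2-fold apart. ATF1 was the farthest apart, at 0.68 higher on the CREB5-labelled array (spot SD 0.09), and CREBL2 was 0.42 higher. The coactivator CRTC3 had a log2 difference of -0.35 and CREB3 of -0.31. Of 18 measured target genes of CREB proteins that respond to cyclic AMP, 0 were 2-fold apart, and the median difference was -0.08, at percentile 3.95 of matched random lists. That median was 0.074 (percentile 9.16) with the normexp background and 0.066 (percentile 43.5) with no filter on dim probes. The circadian repressor PER1 stood at -0.63, the nuclear receptor NR4A2 at 0.55, FOS at -0.41 and CREM at 0.31.

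Among the measured genes, 181 were at least 2-fold higher on the CREB5-labelled array and 197 at least 2-fold lower, while 98.3% lay within 2-fold. Directions rest on the labels. Of the 11 genes named as higher, IFIT1, IFIT2, IFITM1 and IFI44 are known to be induced by interferon. IFIT1, an antiviral RNA-binding protein, was 7.47-fold higher, with a signal of 349 against 56.2. Signals quoted in the text are unscaled, while folds and differences are taken after scaling, so their ratios differ from the folds. IFIT2 was 4.34-fold higher, the antiviral membrane protein IFITM1 3.77-fold and IFI44 3.24-fold. UGT2B15, a glucuronosyltransferase that conjugates androgens, was 4.73-fold higher (signal 1360 against 346), and its relative UGT2B11 was 3.08-fold higher. TCIM, a regulator of WNT signalling, was 6.55-fold higher. BPIFA1, a secreted protein of the airway epithelium, was 4.5-fold higher and KITLG, the ligand of the receptor KIT, 4.27-fold. ACADL, a mitochondrial enzyme of fatty acid oxidation, was 3.90-fold higher, and the condensin subunit NCAPG 2.73-fold. For these 11 genes the spot SD of the log2 difference lay at 0.10 to 0.27.

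On the other side, LRRD1 was 7.33-fold lower on the CREB5-labelled array (a log2 difference of -2.87, but -0.88 with its dim probes included) and RPS19BP1, a partner of the deacetylase SIRT1, was 5.47-fold lower, with a signal of 359 against 2368. CDK5R2, an activator of the kinase CDK5, was 3.56-fold lower. ANXA5, which binds phosphatidylserine, was 3.28-fold lower (signal 2087 against 8246), LYPLAL1 3.22-fold and IGF2R, the receptor that clears insulin-like growth factor 2, 2.68-fold. The pseudogene ATP8B5P was 2.15-fold lower (-1.10, but -0.44 with its dim probes included) and RTL10 2.14-fold. These 19 genes were all that the naming rule kept out of 70 before it required 2-fold under the other background correction, under quantile normalization and in the authors' table. Except for IFIT2 and IFITM1, each rested on 1 detected probe. A further 901 genes were well above background on the CREB5-labelled array alone and 435 on the empty-vector array alone, and the bound reached 2-fold for 128 and 120 of them. On the CREB5-labelled array, WSCD1 was at least 22.9-fold higher, WFDC13 at least 18.9-fold, LEMD1 at least 8.06-fold, LST1 at least 7.46-fold and the complement component C8B at least 7.15-fold. On the empty-vector array, ZCCHC13 was at least 13.0-fold higher, the kinase PAK5 at least 10.7-fold, the small GTPase RHOJ at least 8.37-fold, the olfactory receptor OR2T11 at least 7.79-fold and PTCHD4 at least 7.14-fold. Each gene just named by its bound rested on 1 probe, with a signal of at most 128 on its brighter array. The bounds allow for no spot error, so they are not guaranteed minima.

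The balance of higher and lower calls depended on the scaling. Calls on the higher side made up 47.9% in the main setting, 35.9% (141 higher, 252 lower) after quantile normalization, 33.0% (131 and 266) after loess and 36.4% (130 and 227) in the authors' value table. With the normexp background correction, 22 genes were higher and 19 lower.

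**Figure D1:**
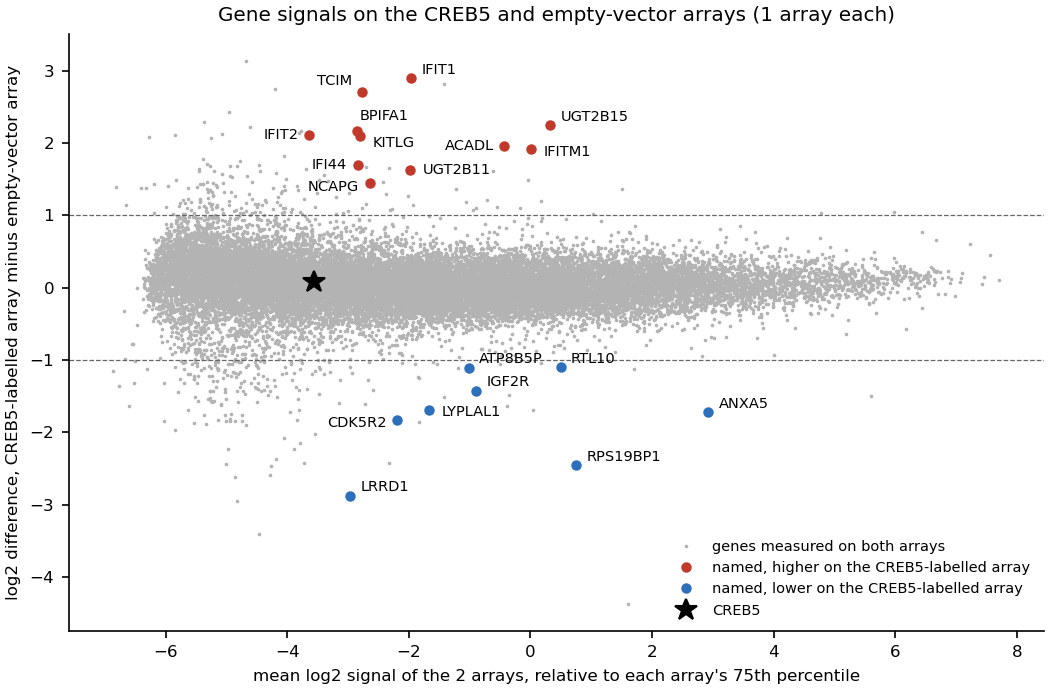
The log2 difference of each gene measured on both arrays (CREB5-labelled minus empty-vector array, vertical axis) is plotted against its mean log2 signal relative to the 75th percentile of each array (horizontal axis), with dashed lines at 2-fold. The 11 named higher genes are red, the 8 named lower genes blue, and CREB5 (0.08) is the black star; gray points spread more widely at low signal.

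Interferon-stimulated genes were higher on the CREB5-labelled array as a group. Of 30 listed genes, 25 were measured on both arrays; 6 were at least 2-fold higher, 0 at least 2-fold lower, and 23 had a difference above 0. The list's median difference was 0.42, above all 10000 random lists of the same size and signal level (percentile 100; random lists had a median of 0.04 and an SD of 0.06). IFIT1 (2.90), IFIT2 (2.12), OAS1 (1.82), an enzyme that activates the antiviral nuclease RNase L, and IFI44 (1.70) were the farthest apart. Outside the naming rule, and chosen after their values were seen, OASL (1.46) and BST2 (1.08), which tethers budding virions, were the others past 2-fold, and IRF7 (-0.58) and USP18 (-0.23) were the 2 members below 0. The ubiquitin-like protein gene ISG15 differed by 0.71 and the antiviral GTPase gene MX1 by 0.13. A further 4 members, also chosen after their values were seen, were well above background on the CREB5-labelled array alone: RSAD2 at least 3.69-fold higher, the chemokine CXCL10 at least 2.46-fold, IFIT3 at least 2.38-fold and SAMD9 at least 1.66-fold. The list's percentile was 100 under each alternative fixed in advance, with medians from 0.29 to 0.59. With the normexp background 3 members were 2-fold higher. Of 7 listed interferon genes, 3 were measured on both arrays, and 0 were 2-fold apart: IFNB1 0.45 (spot SD 0.32), IFNL2 0.06 and IFNL1 0.04. The other 4 were well above background on neither array or had no probe, so a difference in interferon itself stays open.

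**Figure D2:**
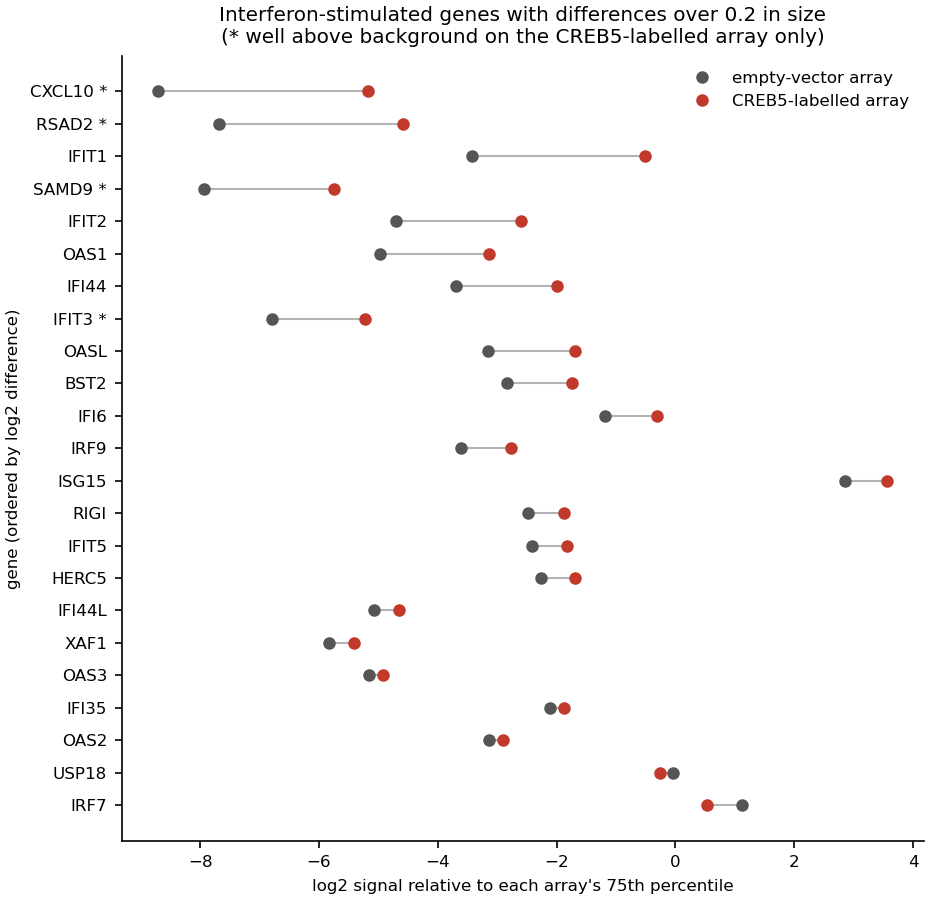
Each line joins the log2 signal (relative to the 75th percentile of each array, horizontal axis) of an interferon-stimulated gene whose difference exceeds 0.2 in size on the empty-vector array (gray) and on the CREB5-labelled array (red), 1 array per condition with no error bars. Genes with an asterisk were not well above background on the empty-vector array, so their gray points mark no measured level; of the others drawn, all but IRF7 and USP18 lie to the right on the CREB5-labelled array.

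Of the 38 gene lists fixed in advance, the interferon-stimulated list was the 1 above the central 95% of its matched random lists. Below the central 95% of theirs lay 8 lists. Chance would put 0.95 on each side if genes varied independently, but some lists share members. The random lists also drew on features other than protein-coding genes, whose median was 0.09 against 0.04 for protein-coding genes. With protein-coding genes alone as background, 6 of the 8 stayed below. Those 8 shifts were small, and directions again rest on the labels. The 10 metallothioneins, which bind zinc and copper, had a median difference of -0.29 (percentile 0.02), with 8 below 0, among them MT1H (-0.50), MT1X (-0.42), MT2A (-0.38) and MT1E (-0.34). Metallothionein genes are close paralogs, and how far their probes cross-hybridise is not known here. They are therefore not 10 independent readings, while the random lists draw each gene separately, so that percentile may look too extreme. The 15 cyclins and cyclin-dependent kinase inhibitors had a median of -0.23 (percentile 0.03) and a mean of -0.09, with 10 below 0 and 5 above. That list also holds the kinases themselves and the retinoblastoma gene family, and is called cyclins and kinases below for short, inhibitors included. CDK2 stood at -0.43, CDKN2C at -0.34, CDK4 at -0.33 and the retinoblastoma gene RB1 at 0.41. The 26 DNA replication and E2F genes had a median of -0.12 (percentile 0.26) with 20 below 0, and the examples farthest apart were MCM2 (-0.50), RRM2 (-0.38), TYMS (-0.37) and MCM4 (-0.37). The 23 mitotic genes had a median of -0.10 (percentile 1.68), with AURKB at -0.79, CENPE at 0.49, AURKA at -0.48 and CDC20 at -0.48. The list of the unfolded protein and amino acid stress response had a median of -0.07 (percentile 1.07; PHGDH -0.47, CHAC1 -0.33), cholesterol synthesis -0.08 (percentile 1.08; MVD -0.37), immediate early and AP-1 genes -0.10 (percentile 2.36; DUSP6 0.50, FOS -0.41) and apoptosis regulators -0.10 (percentile 1.77; BCL2A1 -1.16, BIRC3 0.75). BCL2A1 was the only member of the 8 lists that was 2-fold apart. Only 4 of the 8 (metallothioneins, cyclins and kinases, DNA replication, stress response) stayed below the central 95% under all alternatives fixed in advance. Over the few members with 2 or more measured probes, DNA replication (percentile 21.2), cyclins and kinases (16.3) and the stress response (17.6) lay inside it, and the apoptosis list had a median of 0.048, at percentile 49.4, with the normexp background.

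**Figure D3:**
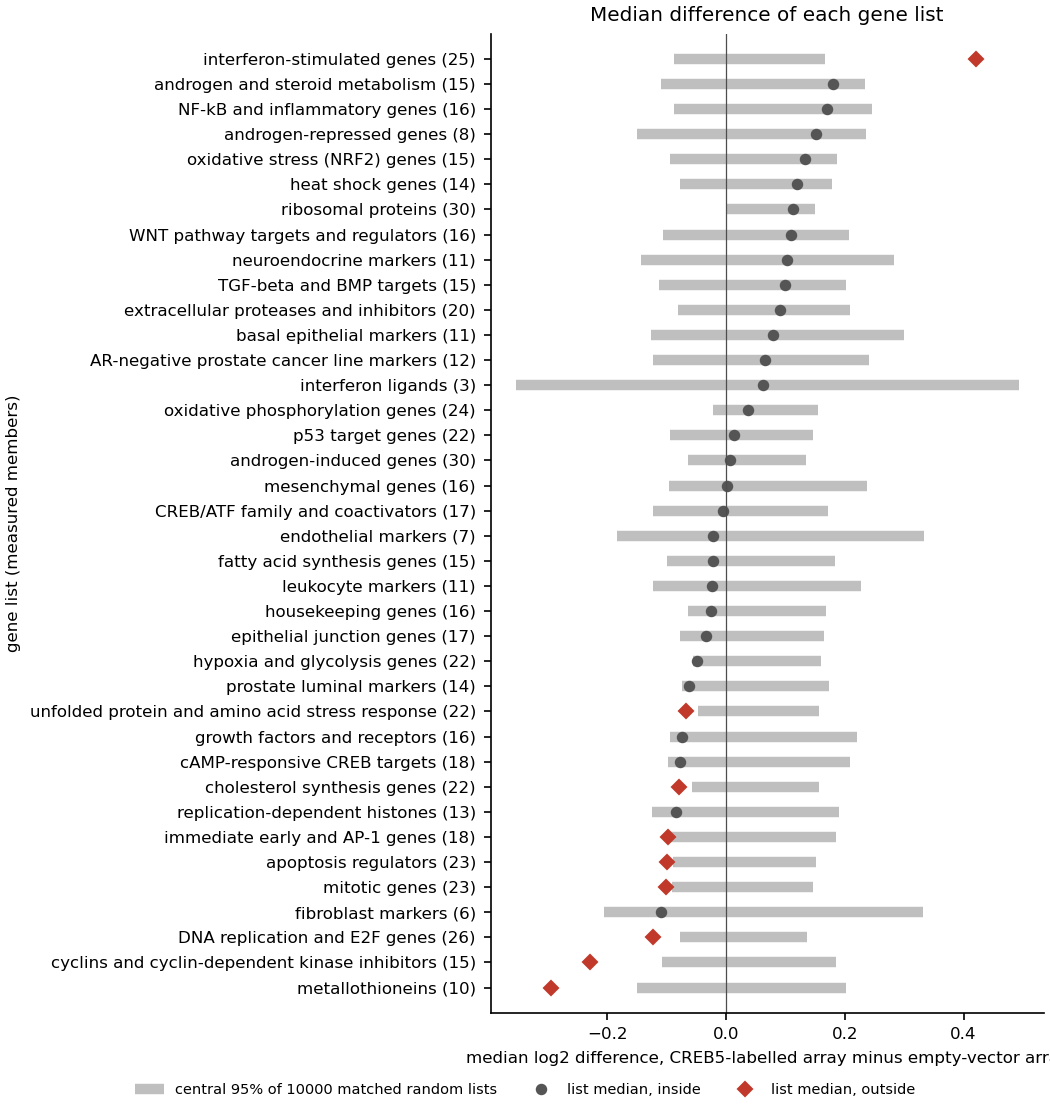
The median log2 difference (CREB5-labelled minus empty-vector array, horizontal axis) of each of the 38 gene lists, with its number of measured genes in brackets, is set against the central 95% of 10000 random lists matched on size and signal level (gray bars). The interferon-stimulated list (0.42) lies to the right of its bar and 8 lists, drawn as red diamonds, lie to the left; the apoptosis list is at 0.048, inside its range, with the normexp background.

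All 30 androgen-induced genes were measured, 0 were 2-fold apart, and the median difference was 0.01 (percentile 28.0), and -0.02 after quantile normalization and after loess. It was -0.05 (percentile 4.84) with the stricter filter on dim probes and -0.22 (percentile 1.16) over the 5 members with 2 or more measured probes. The farthest apart were ADAM7 (0.61), PLPP1 (-0.45), C1orf116 (-0.40) and the kallikrein KLK2 (-0.33). The androgen receptor itself differed by 0.11 and the prostate-specific antigen gene KLK3 by 0.14, both with a spot SD of 0.09 (chosen after their values were seen). Of 8 measured androgen-repressed genes, UGT2B15 (2.24) was the 1 that was 2-fold apart, and BCHE (0.37), MET (0.24) and ST7 (-0.20) followed. UGT2B15 was also the 1 past 2-fold among 15 genes of androgen and steroid metabolism (percentile 90.5, but 98.3 after loess, above the central 95%), ahead of STAR (0.83), HSD3B2 (-0.75) and HSD3B1 (0.71), which had signals under 32. The 14 luminal markers of the prostate had a median of -0.06 (percentile 3.61), with MSMB at 0.64, the keratin KRT18 at -0.45, GATA2 at -0.42 and ACP3 at -0.31. That list was below the central 95% after quantile normalization (percentile 1.17) and loess (0.86), in the authors' table (1.3), with the normexp background (1.68), with the brightest probe (2.42) and over its 5 members with 2 or more measured probes (0.14). Basal markers (11 measured, percentile 46.2) held LAMB3 at -0.92 and TRIM29 at 0.82, and neuroendocrine markers (11 measured, percentile 62.5) held SCG3 at 0.76 and SRRM4 at 0.43. Neither list had a member 2-fold apart.

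Genes of epithelial-mesenchymal state went both ways. Among 16 measured mesenchymal genes, fibronectin FN1 was lower (-1.12) and the receptor TGFBR2 higher (1.03), with ZEB2 at 0.97 and vimentin VIM at 0.82; the list's percentile was 17.6. VIM had signals of 3912 and 5722, while FN1, TGFBR2 and ZEB2 had signals under 27. The 17 epithelial junction genes, all within 2-fold, were led by ST14 (-0.40), CLDN7 (-0.32), TJP1 (0.32) and MARVELD2 (-0.26), at percentile 9.10. Of 20 extracellular proteases and inhibitors, MMP10 (1.18) and MMP7 (1.03) were past 2-fold, followed by the plasminogen activator PLAT (0.70) and MMP2 (0.58), at percentile 63.4. Among 16 growth factors and receptors (percentile 4.39), the growth factor HGF (-1.43, signal 25.5 against 7.87) and IGF2R (-1.42) were past 2-fold. Of 16 NF-kB and inflammatory genes (percentile 85.7, but 98.96 over the 4 left by the stricter filter and 53.9 with the normexp background), the chemokine CCL5 (1.03) was past 2-fold, with CCL20 at 0.77, BIRC3 at 0.75 and CXCL1 at 0.62.

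In the main setting the other lists lay inside the central 95% of their random lists with 0 members 2-fold apart, and their percentiles are given in brackets. For WNT pathway genes (76.0) the farthest apart were AXIN2 (-0.68) and TCF7L2 (-0.57), and for targets of TGF-beta and BMP (75.2) SKIL (0.54) and ID2 (0.51). Heat shock genes (84.4) held HSPA4L at 0.84 and the oxidative stress list (87.4) held GCLC at 0.55; that list was above the central 95% with the stricter filter (98.96) and had a median of -0.11 (11.1) over its 3 members with 2 or more measured probes. The p53 targets (39.7) held AEN at -0.47, hypoxia and glycolysis genes (3.17) BNIP3L at 0.30, and fatty acid synthesis genes (17.5) ACSS2 at -0.34. Ribosomal proteins (85.5), oxidative phosphorylation genes (22.0), histones (6.98) and housekeeping genes (8.85) were led by RPL19 (0.46), SDHA (-0.37), H3C4 (0.34) and B2M (0.48). The histones, with a median of -0.08, were below the central 95% after quantile normalization (-0.17, percentile 1.56) and loess (-0.18, 1.68) and in the authors' table (-0.17, 1.44), and had a median of 0.14 over the 3 with 2 or more measured probes. The interferon genes themselves stood at percentile 47.0. Markers of cells other than LNCaP were measured beside these groups. The percentiles were 9.56 for 6 fibroblast markers, 17.4 for 11 leukocyte markers, 21.1 for 7 endothelial markers and 52.5 for 12 genes of prostate cancer lines without the androgen receptor, and 0 of their members were 2-fold apart.

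A second probe rarely repeated a 2-fold difference. Among 3492 genes with 2 probes measured on both arrays, 78 probes were 2-fold apart, and the partner probe was 2-fold apart in the same direction for 6 of them (7.69%) and had the same sign for 46 (59.0%). Across those genes the differences of the 2 probes correlated with Pearson's r = 0.204 (genes are not independent replicates). Of 4116 genes with 2 or more measured probes, IFIT2 (1.63 and 2.61) and IFITM1 (1.70 and 2.13) were 2-fold higher at every probe and EML5 (-1.29 and -1.20) was 2-fold lower, the last chosen after its values were seen. The 6 probes with a 2-fold partner were both probes of IFIT2, IFITM1 and EML5, so each of these genes was counted at each probe. Of 63 genes called 2-fold that had several probes, 26 had probes pointing in opposite directions. None of 875 measured probes with 10 spots had a mean difference of 2-fold, while 422 of 26347 probes with a single spot (1.60%) did. The 2 sets are not matched on signal. Above a level of 1 lay 269 of the 10-spot probes and 4866 of the single-spot probes, a smaller share.

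**Figure D4:**
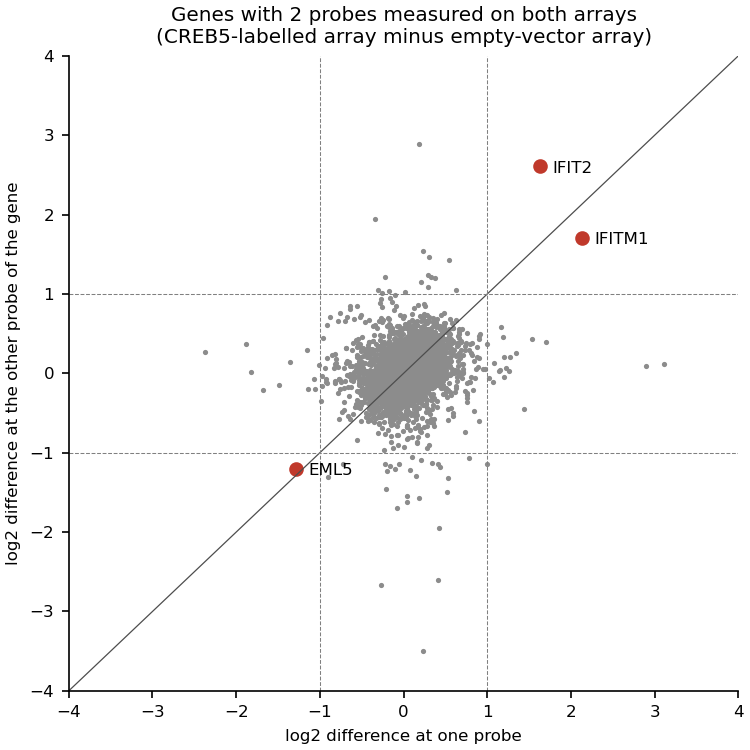
For each of 3492 genes with 2 probes measured on both arrays, the log2 difference (CREB5-labelled minus empty-vector array) at the first probe is on the horizontal axis and that at the other probe on the vertical axis, with dashed lines at 2-fold and equality drawn as a solid line. IFIT2, IFITM1 and EML5 (red) are the genes past 2-fold at both probes.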

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

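In this part the tests of single-spot noise, of a difference between cultures, of the probe's place and of exchanged arrays were chosen after the results were seen. The tests of array scaling and of shared transcript accessions were written before. Of 53 positive control probes outside the comparison, 12 were well above background at every spot on both arrays, with signals of up to 70.7 on the empty-vector array and 58.5 on the other.

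The higher interferon-stimulated genes on the CREB5-labelled array were weighed against scaling, spot noise and culture differences. An artifact of array scaling or of a signal trend is argued against as the whole source. The median, 0.42 in the main setting, was lowest after loess, at 0.29, where the central 95% of random lists ended at 0.12. The lowest percentile over the alternatives fixed in advance was 100. Scaling to the median of detected probes shifts all genes alike, so it could not change that percentile. The random lists are matched on level within each setting, so they carry any trend shared by genes of a level. Quantile normalization and loess were therefore weak tests of that percentile, and the filters and the brightest probe do not alter the scaling. What argues against a trend is the gap to lists of the same level, present in the main setting already. The authors' table nearly repeats quantile normalization (median 0.34 in both). Part of the shift's size depends on the scaling. Spot noise that is independent between genes is argued against as the source of the whole shift: the list was fixed before the data were examined, and its median of 0.42, the same value that drew attention to it, lies far outside the matched random lists that carry this noise (median 0.04, SD 0.06). Probe by probe it stays open, since the genes with several probes were too few to decide. Of these, 3 of 4 (75%) had every probe higher, against 35.0% of all 4116 genes with 2 or more measured probes. OAS2 had probes from -1.69 to 1.88. A difference between the 2 cultures or transfections other than CREB5 cannot be told apart from the effect of CREB5 with 1 array per group, and either may explain the shift.

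The 2-fold differences not shared by a second probe were weighed against spot noise and transcript differences. At matched signal, the rate at which single spots of the 10-spot probes strayed 2-fold from their own mean would give 302 of the 422 single-spot calls (71.5%), so noise of single spots may account for many of the 2-fold calls. That rate counted spots flagged as outliers, while the 422 calls left flagged spots out, so this share may be too high. Probes that read different transcripts are argued against as the main source, since with the same transcript accession on both probes only 6 of 64 partners (9.38%) were 2-fold apart in the same direction. Those 6 were both probes of IFIT2, IFITM1 and EML5. The share expected from spot noise differed by signal. It would give 189 of the 198 single-spot calls between levels of -5 and -3, and 16.2 of the 53 between -3 and -1. Above a level of 1 it would give 1.81 of the 10. Biological differences at the other single-probe genes stay untested.

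The CREB5 probe, at 1.06-fold, did not separate the arrays. A probe outside the cloned part of CREB5 may explain this and cannot be told apart from weak expression of the plasmid, because the place of the probe and the extent of the insert are not known here. An exchange of the 2 arrays cannot be told apart either, since a difference of 0.083 against a spot SD of 0.27 points neither way. The directions of all other results stay tied to the labels.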

How the results depend on the processing

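The CREB5 difference moved by less than its spot SD under each alternative run on it. Of 152 values for the 19 genes named by size, 132 moved by less than the spot SD, 20 moved by more and 0 reversed, but with no filter on dim probes LRRD1 (-0.88) and ATP8B5P (-0.44) were no longer 2-fold apart. The naming rule had already required 2-fold in the same direction with normexp, quantile normalization and the authors' table, so no reversal was possible there. All but IFIT2 and IFITM1 rested on 1 detected probe, which the brightest-probe setting leaves unchanged. These counts are therefore largely fixed by the selection. The protein-coding background, the restriction to genes with 2 or more measured probes and the 2-fold call at every probe were chosen after seeing the data. With the normexp background, 22 genes were higher and 19 lower, the interferon-stimulated list had a median of 0.30 with 3 members 2-fold higher, immediate early genes -0.0096, cyclins and kinases -0.077, and apoptosis regulators 0.048 (percentile 49.4). The median of all genes was then 0.12, against 0.05 in the main setting. With no filter on dim probes, 1143 genes were higher and 555 lower (67.3% higher), the interferon-stimulated median was 0.59 with 10 members 2-fold higher, and immediate early genes were at -0.0031. The stricter filter left 11711 genes, 37 higher and 32 lower, with medians of 0.58 for interferon-stimulated genes and 0.031 for apoptosis regulators (percentile 48.4). Fewer genes were tested there. The interferon-stimulated median was 0.34 after quantile normalization, 0.29 after loess and 0.34 in the authors' table, and that of the unfolded protein list -0.12 in each of these. With the brightest probe, cyclins and kinases were at -0.10 and apoptosis regulators at 0.023 (percentile 37.9). Restricted to genes with 2 or more measured probes, the interferon-stimulated list (4 left) had a median of 0.42 (percentile 99.59), with 1 gene 2-fold higher. In that setting DNA replication genes (6 left) were at -0.038 (percentile 21.2), cyclins and kinases (3 left) at -0.10 (16.3), and apoptosis regulators at 0.034 (49.7). The stress response (4 left, percentile 17.6) and mitotic lists (5 left, 22.8) were then inside the central 95% too, while androgen-induced genes (5 left, -0.22, percentile 1.16) and luminal markers (5 left, -0.27, percentile 0.14) were below it. In the 4 settings where the apoptosis median was above 0 it lay inside the central 95%, so the shift was lost, not turned around. With every probe 2-fold, 2 genes were higher and 1 lower. Other than as stated, the cause was not tested. Of the 8 lists below the central 95%, 4 stayed there under all alternatives fixed in advance and 6 with the protein-coding background, while 5 of 29 lists inside it (luminal, histone, steroid metabolism, NF-kB and oxidative stress) fell outside under at least 1 of those fixed in advance. Low signal limits what the arrays show, since the spot SD was 0.32 below a level of -5 and 0.09 above 1. No paired analysis was possible because each group has 1 array.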

Other observations

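The tests of both lists named here were written before their values were seen, but the lists themselves and the family of UGT2B genes were chosen after the interferon-stimulated and UGT2B15 results were seen.

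Members of the UGT2B family, enzymes that conjugate steroids and other lipids with glucuronic acid, were higher on the CREB5-labelled array. All 4 measured on both arrays were at least 2-fold higher: UGT2B15 at 2.24, UGT2B11 at 1.62, UGT2B7 at 1.55 and UGT2B10 at 1.08. UGT2B4 was well above background on the CREB5-labelled array alone, at least 1.43-fold higher. The median of the 4 was 1.59, and 1.01 with the normexp background. With normexp, UGT2B15 (2.07) and UGT2B11 (1.14) stayed past 2-fold, while UGT2B7 and UGT2B10 did not. The median includes UGT2B15, which prompted the choice of the family, and UGT2B11, already named as higher. Over the alternatives fixed in advance, the filters on dim probes included, which left 3 or 5 members, the family's median ran from 1.01 to 1.62. These genes are close paralogs, and how far their probes cross-hybridise is not known here, so they are not independent readings.

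A wider interferon response was tested as a hypothesis on a second list of interferon-stimulated genes. Of its 30 measured members, TRIM22 (1.11) was 2-fold higher, and GBP3 (0.95), DDX60 (0.94) and CMPK2 (0.68) followed. The median was 0.16, at percentile 97.7 of matched random lists. Over the same alternatives the percentile ran from 83.4 to 97.9, so the shift of this list may be slight, and its place outside the central 95% depends on the setting. As a list, genes of MHC class I antigen presentation were not shifted upward. The 15 genes had a median of -0.01, at percentile 19.8, with 7 above 0 and 8 below, among them TAP2 at -0.27 and ERAP2 at 0.26.

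Among features measured on both arrays, the largest difference was at a probe that could not be given a gene name here, A_32_P113154, with a signal of 8254 on the empty-vector array and 332 on the CREB5-labelled array (log2 difference -4.37). It was chosen after its values were seen.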
